A study of Homo sapiens with 93 samples.

How the data were processed

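H3K36me3, trimethylation of lysine 36 on histone H3, was profiled by CUT&Tag in 93 human lymphoblastoid cell lines, which are B cells immortalised with Epstein-Barr virus. CUT&Tag tethers a transposase to an antibody on chromatin and sequences the DNA it cuts. Per the labels' protocols, cells grew in medium with 20% serum in 4 batches of about 20 to 35 lines, 100000 cells were frozen for each assay, and libraries were amplified with 14 PCR cycles. The labels do not say which line belonged to which batch. All libraries form 1 group with 1 library per line, so no comparison between groups was made, and differences between libraries hold line, culture and technical differences together.

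The deposited count table gives whole-number read counts for 14000 features, named by versioned Ensembl gene identifiers, in each library. HISAT2 2.2.1, bedtools and the hg38 build are named, per the submitters' processing notes, with no role or order; the counted interval, read filters and choice of features are not given in the sources used here. The deposited score table holds normal scores for the same features and libraries. In all 93 libraries the sorted scores are identical and run from -3.92 to 3.92. How the authors made the scores is not given in the sources used here, and they were compared with transforms of the counts.

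No identifier could be paired with a gene symbol (0 of 14000 matched the reference table), and the files do not pair them. The 36 gene lists fixed before the data were examined, division by interval length, matching on length, restriction to autosomes and distances in bases were therefore not used, and the rule for named genes was reduced to 4 identifiers: the 2 called features with the highest and the 2 features with the lowest ratio of own to trended dispersion. In place of the lists, 3 cell cycle marker sets were taken from scran 1.30.0, which ships human marker pairs by Ensembl identifier. For each of G1, S and G2M, the 100 genes that most often came first minus second in the pairs were used. This choice was made after the files had been seen. Adjacent features means adjacent rows of the table, whose order on the genome is not given.

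Counts were scaled with TMM factors from edgeR 4.0.16 (0.916 to 1.05) and expressed as log2 CPM, counts scaled to the library total, with a prior count of 2. Marker set levels were set against all 14000 features, and the other tests across features used the 13915 with at least 10 counts in at least 47 libraries. Main fits had log2 library total and dynamic range as covariates, the dynamic range being the median log2 CPM of the top quintile of features by mean level minus that of the bottom quintile. Features that varied more between lines than the trended dispersion were called with edgeR's deviance goodness-of-fit test and Benjamini-Hochberg adjustment at 0.05. Marker set levels were tested two-sided against 100000 random lists. Set variability (two-sided) and coordination (one-sided, higher) were tested against 10000 lists matched on 10 classes of mean count, and pairs of members under 20 rows apart were left out of coordination. Score correlations used 100000 permutations, and adjacent features were tested with 1000 shuffles of the profiles. The smallest p these can give are 1e-05, 0.0001 and 0.001. Analyses ran in R 4.3.3 and Python 3.11.15.

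A step in the counts along the table was searched in the rows after 1900 up to 3200 after it had been seen. For the size of the step, each library's position was found on the odd rows. The size was then measured on the even rows, by differences between libraries whose positions lay at least 100 rows apart. This size is not 0 in other stretches of the table, so it is read against its values there. Positions given as row numbers or used for even counts were not limited to odd rows, except where stated. Even counts were compared before and after the step over counts of 5 to 299, in a linear model with terms for blocks of 50 rows and for libraries within count classes.

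The scripts were tested on simulated data. Extra spread was planted in 100 features at SD 0.3 log2 and in 100 at SD 0.6. Of these, 96 and 100 were recovered among 13909 tested, with 6 false calls. All features were simulated at the trended dispersion. The 6 false calls therefore do not carry over to real features, which scatter around the trend. With a planted 2-fold step, the median held-out size was 0.99 log2. With none planted, it was -0.00329 log2, above 0 in 43 of 93 libraries, and steps explained 0.188% of the variance; simulated features were independent, unlike adjacent rows of the table.

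Alternatives were DESeq2 1.42.0 size factors and dispersion outliers, robust dispersion, a prior count of 0.5, other filters, other covariates (none, 5 or 10 principal components), leaving out the 10 shallowest libraries and the deposited scores. Those chosen after seeing the data were leaving out the rows after 1900 up to 3200, lists matched on 5 blocks of the table, thinning to the smallest total, and the 46 shallower and 47 deeper libraries apart.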

Results

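H3K36me3 was measured by CUT&Tag in 93 lymphoblastoid cell lines, with 1 library per line. The mark is laid down over the bodies of transcribed genes. Library totals ranged from 2842955 to 24325746 counts, with a median of 14883653 (n = 93). The median count per feature ranged from 114 to 1022 between libraries, and the 10 highest features held 0.942% to 1.31% of a library's counts. Between pairs of libraries the Pearson correlation of log2 CPM across features had a median of 0.967, from 0.887 to 0.99; features are not independent replicates. As a check for a library deposited more than once, counts were compared over 4278 pairs of libraries, and the lowest chi-square per degree of freedom was 5.85. Counting error alone would give a value near 1, and the lowest value lay above that. The statistic also holds any line, culture and technical difference of a pair. Reads amplified by PCR are not independent molecules, so the reference of 1 is approximate.

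The first question was where cell cycle genes stood in the range of H3K36me3. The sets hold genes whose expression marks a phase in a general classifier, and were chosen after the files had been seen. The S and G2M markers lay above the median feature. The 90 measured S markers had a median 0.99 log2 CPM above that of all features (adjusted p = 6e-05, permutation test), and their median was above it in 93 of 93 lines, by 0.95 ± 0.12 (SD). The 93 measured G2M markers lay 0.75 higher (adjusted p = 0.00192), again in 93 of 93 lines, by 0.74 ± 0.15 (SD). The 95 measured G1 markers did not pass the test, with a difference of 0.14 (adjusted p = 0.537). Profiles across features were alike between libraries (median Pearson correlation 0.967), so the lines are not separate tests of these differences. The values are per feature and not per kilobase, so the length of the counted interval enters them.

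The markers of each phase also rose and fell together across lines. The mean pairwise correlation was 0.0843 for the G2M markers, against a median of 0.0107 for count-matched lists (adjusted p = 0.00015). It was 0.0619 for the G1 markers against 0.00661 (adjusted p = 0.00015), and 0.0493 for the S markers against 0.0113 (adjusted p = 0.0009, permutation tests). These correlations were small. Their size depended on the covariates. The G1 excess of 0.0553 over matched lists was 0.145 with no covariates and 0.0158 with 10 principal components removed, and the G2M excess of 0.0736 was 0.179 and 0.0386. Over 9 alternatives the excess ran from 0.0158 to 0.145 for G1, from 0.022 to 0.0612 for S and from 0.0385 to 0.179 for G2M. Each set was past the threshold in each alternative. The lists were matched on mean count only, and no gene set other than the cell cycle markers was tested. Whether phase is the reason for the excess was therefore not tested.

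**Figure D1:**
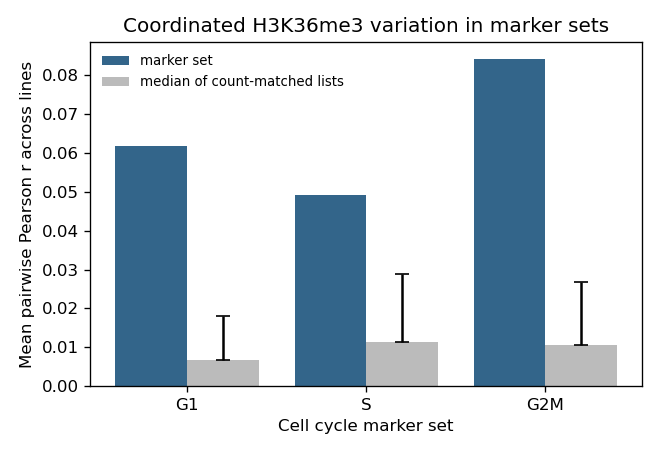
Mean pairwise Pearson r across 93 lines (y axis) for the G1, S and G2M marker sets (blue bars) and the median of count-matched lists (grey bars), whose error bar reaches the upper end of the central 95% of lists. The G2M set stands at 0.0843 and its matched lists at 0.0107.

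Scores of the sets were then compared across lines, in 3 pairs. The G1 and G2M scores had Pearson's r = 0.87 and Spearman's rho = 0.886 (adjusted p = 1e-05 for each, the smallest the permutations can give), and r = 0.853 without the 2 lines farthest from the median. This lay above the central range of random count-matched list pairs, 0.107 to 0.703. It also lay above their own ranges under each of 9 alternatives. Random lists were matched on count and not on coordination within a list, which was lower in them than in the marker sets. A place above or within their range therefore cannot separate a link between 2 sets from coordination within each. The G1 and S scores (r = 0.622, rho = 0.588, r = 0.55 without 2 lines) and the S and G2M scores (r = 0.483, rho = 0.479, r = 0.386 without 2 lines) also had adjusted p = 1e-05, but lay within the ranges of random list pairs, 0.101 to 0.701 and 0.231 to 0.75. This depended on the setting. G1 and S lay above the random range under 3 of 9 alternatives (r = 0.808 with 5 and 0.748 with 10 principal components removed, 0.516 on the deposited scores), and S and G2M under 1 of 9 (r = 0.631 with 10 principal components removed). Among the 46 shallower libraries the S and G2M correlation did not pass the threshold (r = 0.271, adjusted p = 0.0709); among the 47 deeper ones r was 0.672.

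None of the 3 marker sets passed the test for a difference from count-matched features in how much it varied between lines. The median log2 ratio of own to trended dispersion, relative to matched lists, was -0.21 for S (adjusted p = 0.444), -0.16 for G1 (adjusted p = 0.444) and 0.04 for G2M (adjusted p = 0.784). Over all features, 2565 of 13915 varied more than the trend (edgeR goodness-of-fit test), and the median coefficient of variation between lines was 0.141. The called features included 12 of 90 S markers (13.3%), 10 of 95 G1 markers (10.5%) and 9 of 93 G2M markers (9.68%). These shares were below the 18.4% of all features. Median coefficients of variation were 0.12, 0.125 and 0.133. The shares were not matched on count and their difference was not tested. DESeq2's dispersion outliers numbered 269, all of them among the 2565.

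The most variable feature relative to its trend was ENSG00000198502.6, with a coefficient of variation of 1.26 and a dispersion 5.41 log2 units above the trend. ENSG00000179344.16, 3 rows further on in the table, was next, with 0.843 and 4.38. ENSG00000198502.6 had a mean count of 120 and a median CPM of 1.99, against 181 and 14.4 for ENSG00000179344.16. Counts of the former were thus skewed, with high values in a minority of lines. The least variable were ENSG00000179151.13 and ENSG00000179295.18, with coefficients of variation of 0.0425 and 0.0458. The files do not pair identifiers with gene names, and whether these features share reads with near-identical copies was not tested.

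Adjacent features in the table rose and fell together across lines. Their mean correlation was 0.277 ± 0.289 (SD over 13847 pairs), and it was at most 0.0137 in 1000 shuffles of the profiles among features (p = 0.001, permutation test, the smallest it can give). Pairs at least 3000 rows apart had a mean of 0.0048. A correlation above 0.5 was seen in 22.8% of adjacent pairs and 1.66% of distant ones. The mean fell with distance, to 0.176 at 2 rows, 0.0903 at 10 rows and 0.0391 at 100 rows. It was 0.262 in the 46 shallower and 0.296 in the 47 deeper libraries.

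**Figure D2:**
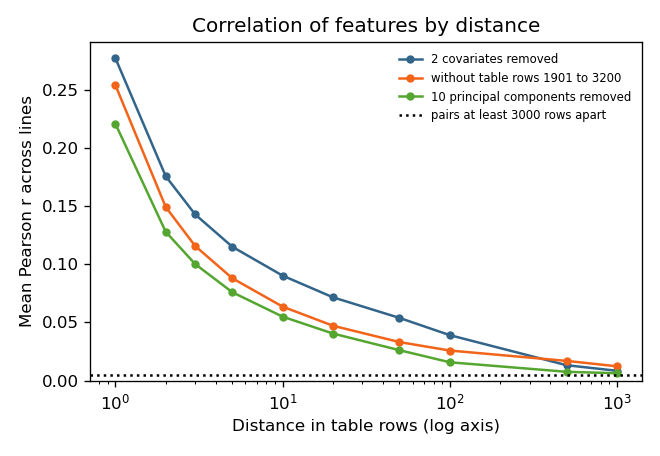
Mean Pearson r across lines (y axis) against the distance between features in table rows (x axis, log scale), with 2 covariates removed (blue), without the rows after 1900 up to 3200 (orange) and with 10 principal components removed (green); the dotted line marks pairs at least 3000 rows apart. The blue line falls from 0.277 at 1 row to 0.0391 at 100 rows.

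Features in the rows after 1900 up to 3200 carried a drop in counts at a row that differed between libraries. The last row before the drop ranged from 2017 to 3047. On held-out rows the drop was 0.84 ± 0.05 log2 (SD, n = 93). Each of these values comes from differences with other libraries, so they are not independent and the SD may understate the spread. The drop explained 26.8% of the centred variance there, against at most 1.95% in 9 other stretches of the table. The same measure could be taken in 7 of these stretches. Its median there was 0.02 to 0.21 log2, and in 4 of them it too was above 0 in all 93 libraries. The size of a drop whose row differs between libraries, and not its sign, thus sets this stretch apart. Both measures rest on differences between libraries, so a change at the same row in all libraries does not enter them. The level also changed elsewhere along the table, as given below. In this stretch, chosen because the drop had been seen there, 605 of 1290 features were called variable, against 1960 of 12625 elsewhere. Values of features in this stretch, in either deposited table, therefore hold this drop as well as any difference between lines. The deposited scores were higher by 1.51 ± 0.42 (SD, n = 93) in the 150 rows before the drop than in the 150 after it.

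The level and the share of even counts changed more than once along the table. Between the first 1900 rows and the rows after 3200 up to 7700 the median log2 CPM went from 5.74 to 4.85 and the even share from 50.6% to 56%. Rows after 7800 up to 8500 stood at 5.91 and 51%, rows after 8600 up to 9400 at 5.10 and 55.9%, and rows after 9600 up to 14000 at 5.77 and 50.8%. These 5 blocks were chosen after the values had been seen.

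**Figure D3:**
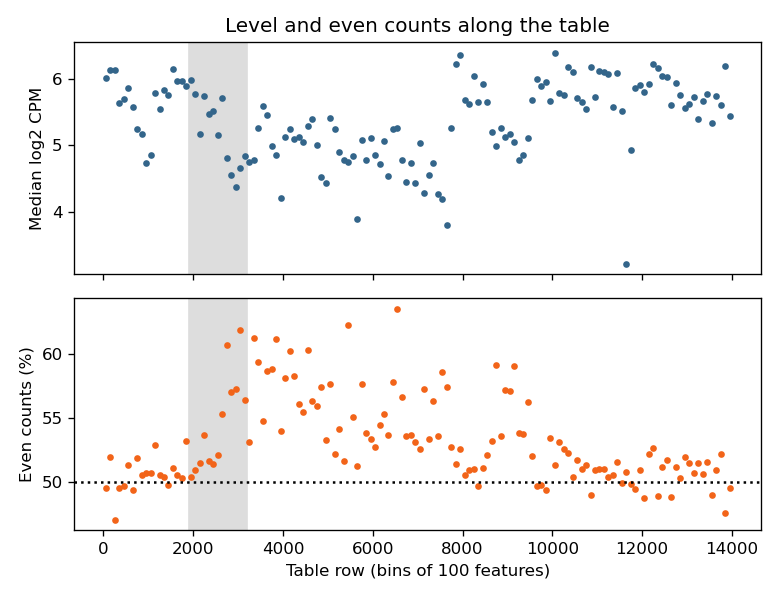
Median log2 CPM (upper panel, y axis) and percent of counts from 5 to 299 that are even (lower panel, y axis; dotted line at 50%) in bins of 100 features along the table (x axis, row number); the shaded stretch is the rows after 1900 up to 3200. Blocks with a lower level, 4.85 in the rows after 3200 up to 7700 and 5.10 in the rows after 8600 up to 9400, have more even counts, 56% and 55.9%.

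Deeper libraries had a smaller dynamic range, with r = -0.495 (rho = -0.448, p = 1e-05 and 3e-05, permutation tests, n = 93; r = -0.421 without 2 libraries). The relation held in the 46 shallower libraries (r = -0.43, p = 0.0027, rho = -0.352, p = 0.0164; r = -0.288 without 2 libraries) and not in the 47 deeper ones (r = 0.0352, p = 0.816, rho = 0.0519, p = 0.729; r = 0.0284 without 2 libraries). The first principal component held 29.9% of the variance and had r = -0.814 with dynamic range, and the second held 12.3% and had r = -0.904 with log2 total.

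**Figure D4:**
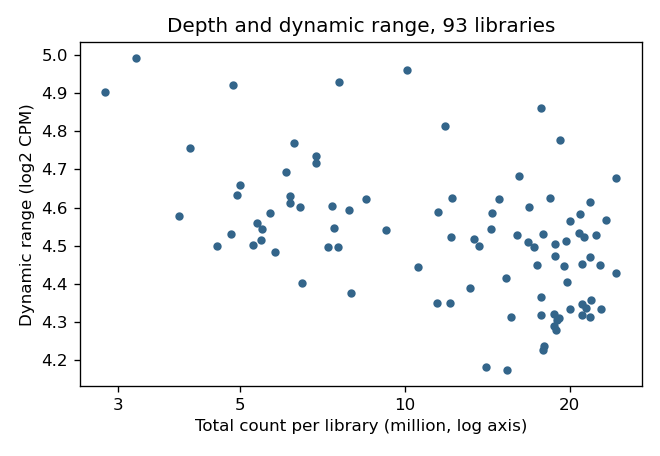
Dynamic range in log2 CPM (y axis) against the total count (x axis, log scale), each point 1 of 93 libraries. Totals run from 2842955 to 24325746 and the dynamic range from 4.17 to 4.99.

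The deposited scores followed the counts closely. Per feature, the Spearman correlation across lines between score and log2 CPM had a median of 0.981, from 0.887 to 0.992, over 13915 features. Standardising log2 CPM per feature and ranking within each library gave values within 0.05 of the deposited score for 94.9% of entries. Against log2 CPM with depth and dynamic range removed, the median was 0.789.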

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

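Leaving out the rows after 1900 up to 3200, lists matched on blocks, thinning and the depth classes were chosen after the data were seen; the other alternatives were fixed before. In 144 cases a tested value kept its direction and side of the threshold, an untested value moved by less than its spread, or a count stayed within 1.5 times the main one. In 5 cases a value changed sign, in 1 a tested value fell short of the threshold, and in 3 a value moved further. The 144 include the named features, chosen as extremes of the same ratio, the cases of robust dispersion, and values short of the threshold in both settings. Their number is therefore no measure of robustness. The count of variable features was 269 by DESeq2's dispersion outliers against 2565, a stricter criterion by construction. It ran from 2163 to 3159 under the other alternatives. Among these, robust dispersion is no separate test. It left the trend and own dispersions used here unchanged, and all 2565 calls were the same. Calls changed more than counts: of the 2565, 1995 were kept with the intercept only, 2104 with 5 and 2011 with 10 principal components. Marker set variability, called under no alternative, changed sign for G2M to -0.0591 with the intercept only and -0.0133 without the rows after 1900 up to 3200, and for S to 0.175 and 0.0219 with 5 and 10 principal components; the cause was not tested. Within the 46 shallower libraries the S and G2M score correlation fell short of the threshold (r = 0.271); the cause was not tested. Depth and dynamic range had r = 0.0352 in the 47 deeper libraries; the cause was not tested. The first component held 26.2% of the variance after thinning. The correlation of scores with counts was 0.789 against residual log2 CPM, which by construction lacks depth and dynamic range. Length-matched lists and length scaling were not run, since no lengths could be assigned. No paired analysis was possible because there is 1 group. Depth limits the shallowest libraries, where the median feature had 114 counts.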

Other observations

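All tests in this part were chosen after the patterns had been seen, and the labels give no group, so no biological explanation was tested against another group.

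The drop in the rows after 1900 up to 3200 is the pattern most in need of a second look. The share of even counts was compared with row block, library and count class removed. It was 5.80 percentage points ± 1.30 (SE) higher after a library's own drop than before it. The highest value over 200 reassignments of positions between libraries was 3.07 (one-sided p = 0.00498, reassignment test, the smallest they can give). With positions found on odd rows the own value was 5.62 ± 1.24 (SE). Taken per library, the difference was 6.21 ± 6.43 points (SD), above 0 in 74 of 93 libraries. Reassigned positions then gave a mean of 5.08 and a highest of 6.33 (one-sided p = 0.00995, reassignment test). Most of this per-library difference thus followed position in the table. A property of the lines such as copy number would leave the even share alone, and the change with row block removed argues against it. The drop lay further down the table in deeper libraries (r = 0.405, p = 7e-05; rho = 0.367, p = 0.00038; r = 0.429 without 2 libraries), also within the 46 shallower (r = 0.432, p = 0.00257; rho = 0.45, p = 0.00193; r = 0.499 without 2) and the 47 deeper (r = 0.404, p = 0.00443; rho = 0.314, p = 0.0319; r = 0.389 without 2, permutation tests). One fixed limit on counts for all libraries would place it earlier in deeper ones, so this argues against such a limit, while another part played by depth stays open. A candidate explanation is a change, along the table, in how reads or mates were counted or in which reads were present, which the files cannot settle. Even counts were more frequent after the drop, where the level was lower. Counting both mates in place of 1 would raise level and even share together, so the values argue against that simplest form.

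The correlation of adjacent rows may have several sources. The drop is not the whole cause, since the mean was 0.254 outside the rows after 1900 up to 3200, and library-wide differences are not, since it was still 0.201 there after removing 10 principal components. Rows 10 apart had a mean of 0.0368 in the same setting. Without coordinates it is not known whether features at either distance overlap. How much of the value at 1 row comes from reads shared by overlapping features therefore stays open. Shared regulation of neighbouring genes stays open and was not tested.

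The smaller dynamic range of deeper libraries is not counting noise alone, since r was -0.468 after every library was thinned to the smallest total. Depth classes that differ in preparation could give such a relation, and cannot be told apart from a trend with depth: r was -0.43 within the 46 shallower and 0.0352 within the 47 deeper libraries, and the labels give no library's batch.

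Few features had lines far below the rest. Of 12597 features with a median count of at least 100, 14 had at least 1 line under an eighth of the median CPM and 3 had at least 3 such lines. The minimum leaves out features that are high in a minority of lines.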
